A study of Homo sapiens with 15 samples.

How the data were processed

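All 15 samples came from HEK293T T-REx cells, a human kidney line that can carry a transgene under tetracycline control. 4 samples were PAR-CLIP libraries, 2 were total nuclear RNA-seq libraries and 9 were ChIP-seq libraries. Groups and replicate numbers followed the sample titles. PHC1 PAR-CLIP, nuclear RNA-seq, PHC1 ChIP and PHC1 dFCS ChIP had 2 libraries each. RNAPII PAR-CLIP had 1 library made with 4-thiouridine (4SU) and 1 made with 6-thioguanosine (6SG), and RNAPII, EZH2, H3K27me3, H3K4me3 and input had 1 ChIP library each. Per the labels, PAR-CLIP cells took up 100 uM of the nucleoside, and 300M cells (M, 1e6) were crosslinked at 365 nm with 0.15 J/cm2. ChIP cells were fixed in 1% formaldehyde for 6 minutes.

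The submitters' processing notes name genome build hg19 for all libraries. They name Bowtie 0.12.7 with SAMtools 0.1.19 for PAR-CLIP, TopHat2 2.0.11 for RNA-seq and Bowtie2 2.2.3 with SAMtools 0.1.19 for ChIP-seq, and R 3.1.0, 3.2.2 or 3.3.0 for later steps. The cluster caller and its conversion filter are not stated, nor are the counter of RNA reads, the window around the TSS and the handling of duplicates.

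The deposited RNA-seq table holds counts, 1 whole read count per gene and library, for 14432 genes named by Entrez number. A further 1 value column of that table was not used. The deposited ChIP table holds a score per gene, by the authors a library-scaled read number at the TSS minus the same for the input. For EZH2, H3K27me3, H3K4me3 and RNAPII every value was found to be a whole read number, scaled to 10M reads of a whole library size, minus the input's, within a tolerance of 1e-08. That decoding gave back the input reads, so values before input subtraction are given as reads per 10M. The authors' PHC1 and PHC1 dFCS columns each join 2 replicates into 1 score. These columns could not be split, how they were joined is not stated, and they are given below as the authors' mean or value, with no SD or n. The design had foreseen TSS read counts with replicates and edgeR for ChIP, and the scores allowed only ratios without a replicate test. The deposited PAR-CLIP tables give, for each cluster, a signal, the mean read coverage per base over the cluster, not scaled to depth. Its product with the cluster's length was a whole number in 100% of clusters of each library.

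Gene regions and their hg19 positions were those of the deposited ChIP table. Symbols were matched by Entrez number for 14378 of the 14432 genes, from a RefSeq table used for names and gene types alone, because its positions belong to a later build. The 54 others are named by number. Among the genes, 12947 were protein coding and 907 were lncRNA genes. A cluster on either strand, since the gene table gives no strand, was given to the region with the nearest start at or before its midpoint. It counted only if that region also reached the midpoint. Where regions overlap, a cluster thus went to a single region at most, and other regions that hold it did not count it. The summed coverage of the clusters was added per gene.

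PAR-CLIP sums and RNA counts were scaled to per-million values with TMM factors (edgeR 4.0.16). They were compared with limma 3.58.1 on log2 of the value plus a pseudocount of 1, with a trend and robust empirical Bayes. Genes needed a per-million value of 5 or more in at least 2 libraries. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, 2-sided. The design had edgeR for these fits if the values were counts. Summed coverage is no read count, so limma was used, and edgeR and DESeq2 1.42.0 were run only on the number of clusters per gene. These p-values measure only the spread between these libraries, which may be technical. Where 1 library stood alone in a group, it was assumed to vary like the replicated group.

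For the pooled ChIP columns the log2 ratio of dFCS over PHC1 was taken on values before input subtraction, with a pseudocount of 0.0637 reads per 10M. The median of a gene list or set was placed among 10000 random lists of the same size, drawn within 20 bins of mean ChIP value or, as an alternative, of nuclear RNA. Percentiles under 2.5 or above 97.5 were taken as outside the random range. Intervals of shares are 95% Wilson intervals, and intervals of medians are 95% order-statistic intervals over genes. Intervals of differences and of partial correlations are 95% bootstrap intervals over genes, with 2000 and 200 draws. They cover counting error or the spread among genes only, not the spread between replicates. Chromatin classes needed H3K27me3 or H3K4me3 of at least 2.0 times the input reads. ChIP over input was log2 of the value plus 1 CPM (counts scaled to a library of 1e6) in both. Correlations across TSS are Spearman's rho over genes, which are not independent replicates, and carry no p. As a background for the shared input, the reads of 1 target of each pair were shuffled 100 times among genes before division by input. Cluster overlap was counted with bedtools 2.31.1 on the same strand with at least 1 base shared. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.

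18 gene lists were fixed, with the tests and the rule for named genes, before the data were examined. They were immediate early and stress genes, heat shock, the unfolded protein and integrated stress response, p53 targets, HOX genes, developmental transcription factors, ribosomal proteins, replication histones, Polycomb members, splicing factors, snoRNA hosts, nuclear lncRNA, housekeeping genes, and neuronal, fibroblast, blood, hepatocyte and keratinocyte genes. Lists with at least 5 measured members were tested with camera (preset correlation of 0.01) and fry. With an estimated correlation camera also takes its degrees of freedom from the few libraries of a fit, so hardly any list could pass in that setting. Camera compares a list with the other genes, while fry asks whether its genes move on balance one way and does not compare it with other genes. The named genes were, for each comparison, the 10 highest and 10 lowest folds among genes that passed the threshold, whose libraries did not overlap between groups and whose mean was at least 20. Up to 4 members of each list with the smallest p, and PHC1, RNF2, EZH2 and POLR2A, were added. Without a test the log2 ratio alone ranked them, and for the chromatin classes up to 4 members of each list were taken by PHC1 over input. PHC1 itself has no row in the deposited tables. Some genes that the rule names are not reported here.

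The methods were tested on simulated data. With changes of each size placed in 100 genes with a mean of at least 20, the limma comparison of PHC1 PAR-CLIP with RNA recovered 73% of 2-fold and 100% of 4-fold changes among 8874 genes, with 0 false calls. The comparison with both RNAPII libraries recovered 0 of 100 changes among 8193 genes at 2-fold and at 4-fold, with 0 false calls. The spread given to the simulated values, a robust SD of the real log2 values, was 1.18 for the RNAPII libraries and 0.202 for the PHC1 libraries. On cluster numbers at 4-fold, edgeR recovered 57.8% with 1 false call and DESeq2 33.2% with 0 false calls, of 199 changes among 6435 genes. The simulated cluster numbers were not given the spread of the real RNAPII libraries. Their false calls therefore cannot tell how many calls on the real cluster numbers are false.

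Alternatives were other size factors or none, other low-value filters, leaving out each library, the 4SU library as the only control, a replicate block for PHC1 PAR-CLIP against RNA, other pseudocounts, cluster numbers, covered length, mean coverage, 1 strand alone and leaving out the deepest 0.1% of clusters. For ChIP they were another scaling, input minimums, class thresholds and matching. Strand, alignment quality and base conversion in reads were not analysed here.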

Results

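PHC1 is a member of Polycomb repressive complex 1 (PRC1), which represses genes and is known to act with PRC2, the complex of EZH2, SUZ12 and EED that places H3K27me3. The series asks where PHC1 binds RNA and where PHC1, with or without its FCS zinc finger, sits at promoters. All 15 samples came from HEK293T T-REx cells, a human kidney line with an inducible transgene. 4 samples were PAR-CLIP, in which a photoreactive nucleoside taken up by cells lets light crosslink RNA to protein, so that RNA bound to 1 protein can be sequenced. PHC1 had 2 PAR-CLIP libraries, and RNA polymerase II (RNAPII) had 1 made with 4SU and 1 made with 6SG. Total nuclear RNA-seq had 2 libraries. ChIP-seq had 2 libraries of PHC1, 2 of PHC1 dFCS, which by its name lacks the FCS part, and 1 each of RNAPII, EZH2, H3K27me3, H3K4me3 and input.

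PHC1 PAR-CLIP gave 696186 clusters in replicate 1 and 698056 in replicate 2, covering 29.3 and 29.1 Mb at a mean coverage of 38.6 and 29.3. RNAPII gave 667937 clusters over 25.0 Mb with 4SU, and 45259 clusters over 1.79 Mb with 6SG, at a mean coverage of 45.3 and 62.4. In PHC1 replicate 1 the 10 deepest clusters held 22.6% of all summed coverage, against 3.72% in replicate 2, 4.07% in the 4SU library and 10.5% in the 6SG library. The RNA libraries held 47187882 and 49626658 reads counted in genes. The decoded ChIP libraries held 34.4M reads for EZH2, 43.1M for H3K27me3, 42.9M for H3K4me3, 32.5M for RNAPII and 38.7M for input (M, 1e6). Their median reads per TSS were 20, 18, 146, 34 and 22, so single TSS values of all targets but H3K4me3 rest on few reads.

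PHC1 clusters recurred between replicates. 66.4% of the replicate 1 clusters shared at least 1 base on the same strand with a replicate 2 cluster, and 70.2% of the replicate 2 clusters with a replicate 1 cluster. By contrast, 28.8% and 27.7% of the PHC1 clusters met an RNAPII 4SU cluster. Summed per gene, the PHC1 replicates had a Spearman correlation of 0.973 across all genes of the table. Replicate 1 had 0.888 with RNAPII 4SU and 0.835 with nuclear RNA replicate 1, and RNAPII 4SU had 0.911 with the latter. By the midpoint rule, 53.6% and 53.4% of PHC1 clusters, 56.0% of 4SU and 52.8% of 6SG clusters were given to a gene region. 2 of the deepest sites in genes lay at the same places in both PHC1 libraries. UNC45B, which encodes a chaperone of muscle myosin, had clusters on chromosome 17 at bases 33478125 to 33478227 and 33478236 to 33478356 in replicate 1, and at 33478239 to 33478251 and 33478253 to 33478264 in replicate 2. DLG2, which encodes a postsynaptic scaffold, had clusters on chromosome 11 at bases 85195044 to 85195306 in replicate 1 and 85195057 to 85195087 in replicate 2, on the plus strand. In replicate 1 bases 85195044 to 85195136 also held a deep cluster on the minus strand.

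The next comparison asks which genes' RNA PHC1 bound more or less than its amount in the nucleus would give. PHC1 PAR-CLIP signal was low over nuclear RNA at most ribosomal protein, heat shock, immediate early, developmental and housekeeping genes. It was high in summed coverage at the 4 nuclear lncRNA measured, of which MALAT1 and TUG1 were low when clusters were counted instead, and at some Polycomb genes, while other Polycomb genes were low. The lists were not matched on gene length, and the median log2 fold of all genes was itself -2.26 in the shortest decile by length. SUZ12, a core PRC2 subunit (Entrez 23512, chromosome 17, bases 30264044 to 30328057), had a per-million value of 2095 ± 179 in PAR-CLIP and 212 ± 9.26 in RNA (SD, n = 2 each). Its log2 fold was 3.3 ± 0.0834 (SE), from 16489 and 15779 covered bases at a mean coverage of 45.0 and 51.4. PCGF6, a subunit of a variant PRC1, was higher by a log2 fold of 2.70 ± 0.102, EZH2, the H3K27 methyltransferase, by 1.92 ± 0.0503, and POLR2A, the largest subunit of RNAPII, by 2.15 ± 0.161. MYC, a growth-promoting transcription factor (Entrez 4609), was lower by a log2 fold of -3.82 ± 0.125, at 6.69 ± 0.652 in PAR-CLIP and 108 ± 0.0949 in RNA. Of 9362 genes tested, 3319 were higher and 4408 lower in PHC1 PAR-CLIP (limma).

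The highest folds were at genes with very little nuclear RNA. Whether the signal at each of them comes from RNA of that gene was not tested. UNC45B (Entrez 146862) had a per-million value of 26749 ± 23870 in PAR-CLIP against 0.738 ± 0.466 in RNA, a log2 fold of 13.57 ± 0.790, from 297 and 201 covered bases at a mean coverage of 55294 and 17940. PID1, an adaptor that binds phosphotyrosine sites, was higher by 9.25, PPEF2, a phosphatase of the retina, by 9.16, and SLC25A43, a mitochondrial carrier, by 8.42. DLG2 was higher by 8.06, CPNE7, a calcium-binding copine, by 7.51, CCL5, a chemokine, by 7.51, and GAL3ST1, a sulfotransferase of sulfatide synthesis, by 7.48. LINC00273 was listed at 0 in both RNA libraries, so it is given no fold. GAL3ST1 had 66 and 64 clusters over 3073 and 3168 bases at a mean coverage of 33.5 and 34.3, while PID1 had 98.7% and 46.4% of its PHC1 coverage in its largest cluster. The lowest folds were at INSIG1, a sterol-sensing brake on cholesterol synthesis (-7.00), COL2A1, the collagen of cartilage (-6.24), UBL4A, a factor in insertion of membrane proteins (-6.04), PPP1R26 (-5.99), B4GAT1, a glycosyltransferase (-5.83), BEX1 (-5.78), GPX1, a glutathione peroxidase (-5.74), and COL6A1, a collagen of muscle matrix (-5.69). ALDH1B1 and ZCCHC12 also passed the test and were listed at 0 in both PAR-CLIP libraries.

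Among stress genes, the immediate early list had 1 member higher and 16 lower of 24 measured, with a median log2 fold of -1.80 (camera adjusted p = 0.0147, and 0.614 with an estimated correlation). Lower members included MYC, while KLF10, ARC and FOS, each known to be induced within minutes of a stimulus, were listed at 0 in PAR-CLIP with per-million values of 17.1, 6.48 and 6.09 in RNA. Of 17 heat shock genes 1 was higher and 14 lower, with a median of -1.79 (adjusted p = 0.0147, and 0.614 with an estimated correlation), among them the chaperone HSPA8 (-4.20), the collagen chaperone SERPINH1 (-3.36), the co-chaperone FKBP4 (-3.27) and DNAJA1 (-1.50). The unfolded protein and integrated stress list went both ways, with 4 higher and 5 lower of 10 (adjusted p = 0.722). SESN2, a stress-induced regulator of growth signalling, was higher by 2.37, HERPUD1 by 1.24 and the asparagine synthetase ASNS by 0.99 (-0.11 on cluster numbers, a measure chosen after the data were seen), and the chaperone gene DNAJB9 was lower (-1.59). Of 10 p53 targets 2 were higher and 7 lower (camera adjusted p = 0.299, fry adjusted p = 6.8e-04). MDM2, the ligase that degrades p53, was higher by 1.08 but stood at -1.0 on cluster numbers, and the cell cycle inhibitor CDKN1A (-3.56), the cell death gene PMAIP1 (-1.78) and SESN1 (-1.25) were lower.

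Of 28 developmental transcription factors 0 were higher and 23 lower, with a median of -2.44 (adjusted p = 0.00165, and 0.614 with an estimated correlation). FOXA1, a pioneer factor of endoderm, was lower by a log2 fold of -3.94, and MSX2, FOXD3 and LHX2 were listed at 0 in PAR-CLIP. HOX genes, which set body position, had 4 higher and 9 lower of 19 (camera adjusted p = 0.670, fry adjusted p = 0.00882), with HOXA11 at -4.35 and HOXD13 at -2.43, and HOXB13 listed at 0 in PAR-CLIP. Of 48 ribosomal protein genes 1 was higher and 45 lower, with a median of -2.48 (adjusted p = 2.73e-07, and 0.614 with an estimated correlation of 0.55), such as RPL11 (-3.66), RPS21 (-3.15), RPL6 (-3.09) and RPL27 (-2.11). Housekeeping genes had 1 higher and 9 lower of 10, with a median of -3.07 (adjusted p = 0.0169, and 0.614 with an estimated correlation): lactate dehydrogenase LDHA (-4.27), tubulin TUBA1B (-3.76) and the glycolytic PGK1 (-2.50) were lower, and HPRT1, an enzyme of purine salvage, was higher by 1.93. All 3 replication histones measured were lower, H2BC21 (-2.97), H2BC5 (-2.75) and H3C10 (-2.74). Both measured snoRNA hosts were lower, SNHG10 (-4.37) and SNHG33 (-2.57). No camera call named here held with an estimated correlation, but that setting also cuts the degrees of freedom to those of the few libraries. For developmental factors the estimate was 0.0177, near the preset of 0.01, yet the unadjusted camera p went from 3.3e-04 to 0.0796. It therefore cannot tell whether correlation among genes removes these calls. The counts adjusted over the list alone were the same as over all genes for every list.

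All 4 measured nuclear lncRNA were higher in summed coverage: OIP5-AS1 (2.38), the paraspeckle RNA NEAT1 (2.32), the speckle RNA MALAT1 (1.82) and TUG1 (0.92). On cluster numbers MALAT1 stood at -4.70 and TUG1 at -0.67. Polycomb members had 9 higher and 8 lower of 22, with a median of 0.03 that lay above that of all genes (camera adjusted p = 0.532). By fry, which tests a list against no change, they were on balance higher (adjusted p = 0.00514). SUZ12, PCGF6 and EZH2 were among the higher ones, RNF2, the catalytic ubiquitin ligase of PRC1, was higher by 0.42, and CBX8, a chromodomain subunit of PRC1, was listed at 0 in PAR-CLIP. Splicing factors had 8 higher and 11 lower of 25, with a median of -0.12 and a camera direction above the other genes (adjusted p = 0.798). LUC7L3 (2.03, and -0.27 on cluster numbers) and TRA2A (1.79) were higher, and SRSF3 (-1.72) and the branch point protein SF3B1 (-1.63) lower. Of 3 neuronal genes, the RNA-binding protein gene ELAVL3 was higher by 5.78, and the neurofilament genes NEFL (-3.34) and INA (-2.67) were lower. The hepatocyte gene ALB, an abundant plasma protein of liver, was higher by 2.76 at a per-million value of 6.45 ± 1.23 in PAR-CLIP. No fibroblast, blood or keratinocyte marker passed the low-value filter, and their median levels in RNA were 0.212, 0.0954 and 0.0212 CPM in replicate 1.

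The median log2 fold of all genes was -0.33 with TMM and -0.72 with totals alone, which left 2579 genes higher and 5148 lower, so folds are relative to the chosen scaling. Without TMM the Polycomb list had 8 higher and 11 lower members and RNF2 stood at 0.07. Genes lower fell to 2779 without RNA replicate 1 and to 2780 without RNA replicate 2. With a replicate block 3255 genes were higher and 4423 lower. The fold rose with gene length (Spearman 0.31 across genes), from a median of -2.26 in the shortest decile (3.68 kb) to 0.15 in the longest (280 kb), and PAR-CLIP clusters were counted over gene regions by the midpoint rule.

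**Figure D1:**
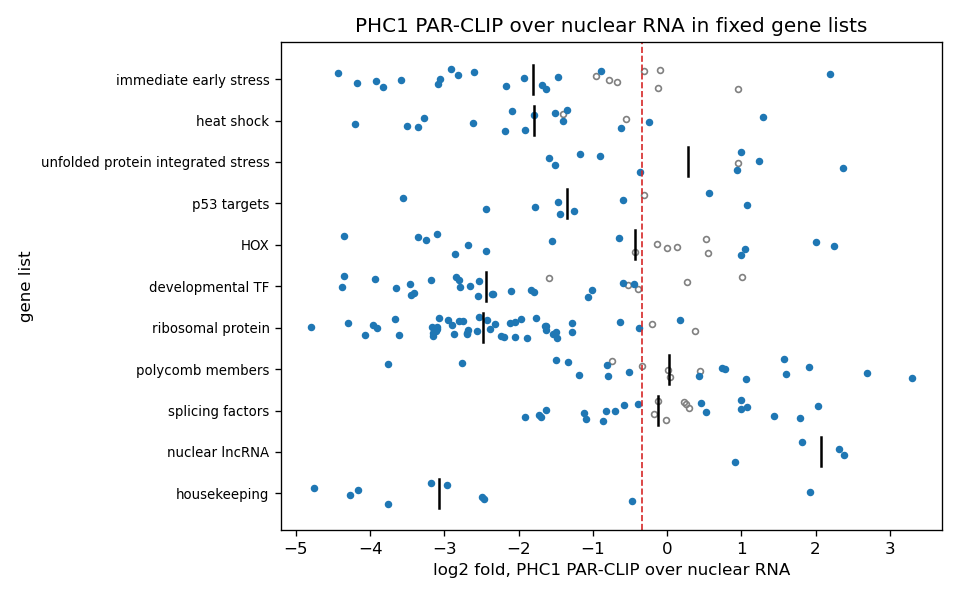
Log2 fold of PHC1 PAR-CLIP over nuclear RNA (x axis) for the measured genes of each fixed list with at least 4 of them (y axis). Each point is a gene, filled where its adjusted p passed 0.05 and open where not, black bars are list medians and the dashed line is the median of all genes (-0.33); the ribosomal protein median is -2.48 and the nuclear lncRNA median 2.07.

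The comparison with RNAPII PAR-CLIP asks whether PHC1 bound RNA differently from the polymerase, which contacts RNA as it is made. The design took both RNAPII libraries as the control pair, and in it no gene passed the threshold. SUZ12 had per-million values of 1895 and 2138 in PHC1 against 597 with 4SU and 859 with 6SG, a log2 fold of 1.49 ± 0.292 (SE, adjusted p = 0.150), which was -0.04 on mean coverage per covered base, a measure chosen after the data were seen. MYC had 6.88 and 5.99 against 122 and 291, a log2 fold of -4.67 ± 0.631 (adjusted p = 0.146). limma called 0 genes higher and 0 lower of 8435, with 1195 higher and 648 lower at an unadjusted p under 0.05. On cluster numbers per gene edgeR called 1211 higher and 1083 lower of 6556, and DESeq2 called 3 higher and 3 lower. The 4SU and 6SG libraries differed in nucleoside and in depth, correlated at 0.775 across genes, and on simulated data limma recovered 0 of 100 changes at 4-fold in this comparison. The simulated cluster numbers lacked the spread between the RNAPII libraries, so they cannot tell how many of the edgeR calls on cluster numbers are false.

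Of the lists in that comparison, camera placed 4 below the other genes. They were immediate early genes (16 measured, median -1.09, adjusted p = 0.00307), splicing factors (25, median -0.26, adjusted p = 0.00307), developmental transcription factors (14, median -1.26, adjusted p = 0.00612) and HOX genes (14, median -0.35, adjusted p = 0.0420). With an estimated correlation each had an adjusted p = 0.738 by camera. That setting rests on the degrees of freedom of the few libraries, so it cannot tell whether correlation removes these calls. By fry, which does not compare a list with other genes, developmental factors were on balance below 0 (adjusted p = 0.0211) and Polycomb members above 0 (adjusted p = 0.0428). Against 4SU alone the medians of these lists were -0.49 and 0.19, and neither fry call held. No member of any list passed over all genes. Adjusted over the list alone, MYC fell, and HPRT1, OIP5-AS1, ELAVL3 and ALB rose, each the single call of its list, since ALB was the only hepatocyte gene measured, and it was listed at 0 with 6SG. Of the 8435 genes 2186 were listed at 0 with 6SG, so that their folds against both controls rest on the pseudocount, among them 6 of 17 heat shock, 12 of 45 ribosomal protein and 5 of 9 p53 genes. Heat shock genes had a median of 1.50 and a mean of 0.94 while camera placed them below other genes (adjusted p = 0.666). The same held for ribosomal proteins (median 0.82, adjusted p = 0.579). The unfolded protein list (median 0.44, adjusted p = 0.666) and housekeeping genes (median 0.57, adjusted p = 0.988) had medians below that of all genes, as camera placed them. Against 4SU alone, a setting chosen for lists after the data were seen, these 4 medians were -0.71, -0.79, -0.21 and -0.38, in that order. Polycomb members had a median of 0.53, below that of all genes, with 8 of 20 above the latter and EZH1 at -1.82, while camera placed them above other genes (adjusted p = 0.659), and p53 targets had a median of 1.60 (adjusted p = 0.662). Neuronal genes had a median of -1.02 and a mean of 0.17 over 3 members, replication histones a median of 0.49 over 3, and nuclear lncRNA of 0.47 over 4. Against 4SU alone these medians were 0.27, -1.0 and -0.35. The snoRNA host SNHG10 was listed at 0 with 6SG and is given no fold against both controls. RNF2 stood at 0.65 and EZH2 at 0.54, which were -0.59 and -0.53 on mean coverage, and POLR2A at 0.19, which became -0.07 without TMM and -0.09 with 4SU alone, and the median of all genes was 0.59 with TMM and 0.36 without.

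With the 4SU library as the only control, a setting fixed in advance but with no replicate of the control, 2707 genes were higher and 2248 lower in PHC1 of 8037. These calls, and those of the lists below, hold only if the lone 4SU library varies like the PHC1 pair. The RNAPII libraries, which differ in nucleoside and depth, had a spread of 1.18 against 0.202 for PHC1 (robust SD of log2 values), and with both as controls limma called no gene, as given above. VIL1, an actin-bundling protein of gut epithelium, was higher by a log2 fold of 5.81 ± 0.384 (SE), at per-million values of 90.5 ± 4.57 in PHC1 (SD, n = 2) and 0.626 with 4SU. The kinase gene MAP3K19 (5.63), SPMAP1 (5.30) and CCL5 (5.17) were higher too. GAL3ST1, the chemerin receptor CMKLR2, NMRK2, an enzyme of NAD synthesis, ACOX2, a peroxisomal oxidase, and C1orf146 passed the test and were listed at 0 with 4SU. TEX15, a gene of germ cell development, was lower (-4.53), as were C22orf46P (-4.19), the chromatin remodeller SMARCA1 (-4.16), MYC (-4.04), TTC13 (-4.0), MDM1 (-3.86), the endocytic receptor LRP2 (-3.75), the zinc finger gene ZNF711 (-3.73), the membrane scaffold ANK3 (-3.72) and CCDC112 (-3.60). With the 6SG library as the only control ANK3 stood at 0.31 and MAP3K19 at -0.03. LRP2, CCDC112, C22orf46P and SMARCA1 were listed at 0 with 6SG, a library of far fewer clusters, so their folds there rest on the pseudocount. MYC had 194 and 158 covered bases in PHC1 at a mean coverage of 13.9 and 14.4, and 1145 bases at 68.2 with 4SU. SUZ12 had 16489 and 15779 bases at 45.0 and 51.4, and 6176 bases at 62.2 with 4SU, so its higher sum came with more covered bases.

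The list tests in that setting were chosen after the data were seen. With an estimated correlation no list passed camera, but with so few libraries hardly any could. Polycomb genes had 10 higher and 4 lower of 20 (camera adjusted p = 0.404). PCGF6 (2.51), SUZ12 (1.75), AEBP2, a PRC2 cofactor (1.62), RNF2 (1.14) and EZH2 (0.56) were higher, and EZH1 (-1.58) was lower. Splicing factors had 2 higher and 20 lower of 25 (adjusted p = 1.7e-04), with SRSF7 (-1.93), SF3B1 (-1.57) and HNRNPH1 (-1.56) lower and HNRNPC (1.22) higher. Ribosomal protein genes had 8 higher and 25 lower of 45 (adjusted p = 0.0158), among them RPL34 (2.43), RPS6 (-1.93), RPL19 (-1.40) and RPL7 (-2.92). Heat shock genes had 1 higher and 9 lower of 16 (adjusted p = 0.0164): HSPH1 (-2.36), FKBP4 (-1.51) and CHORDC1 (-1.42) were lower and DNAJB4 (1.45) higher. HOX genes had 0 higher and 6 lower of 13 (adjusted p = 0.0363), such as HOXA13 (-1.77), HOXD10 (-1.37), HOXA3 (-1.29) and HOXC8 (-1.01). Immediate early genes had 1 higher and 5 lower of 15 (adjusted p = 0.118), with IER5 (-2.12), the growth arrest gene GADD45A (-1.66) and the survival gene MCL1 (-0.90) lower. Stress genes of the unfolded protein list had 4 higher and 3 lower of 11 (median -0.21, mean 0.30, adjusted p = 0.966), among them the pseudokinase gene TRIB3 (4.01), SESN2 (1.85), the transcription factor XBP1 (1.77) and ASNS (-1.12). Of 9 p53 targets 2 were higher and 2 lower (median 0.00, mean 0.09, camera below other genes, adjusted p = 0.966), with MDM2 at 0.78, BTG2 at 1.59 and PMAIP1 at -0.74. Of 9 developmental factors TBX3 alone was lower (-2.62, list adjusted p = 0.359), and it was listed at 0 with 6SG. Of 10 housekeeping genes 1 was higher, HPRT1 (1.79), and 4 lower, among them GAPDH (-1.18), TBP (-1.12) and LDHA (-1.08), with 3 lower adjusted over the list alone (adjusted p = 0.404). OIP5-AS1 was higher (2.28) and TUG1 lower (-0.63), while MALAT1 (-1.50) and NEAT1 (-0.07) did not pass, a list median of -0.35 with a mean of 0.02. H2BC5 (-1.53), H2BC21 (-1.0) and SNHG10 (-0.97) were lower, ELAVL3 (4.15) and ALB (1.54) higher, and NEFL (-2.08) lower. Except for that housekeeping count, the counts adjusted over the list alone were the same as over all genes. With the 6SG library as the only control the folds of SF3B1 (1.27), CHORDC1 (0.50), RPL19 (2.77), H2BC5 (1.72), TUG1 (0.84) and MALAT1 (3.12) were above 0. FKBP4, RPS6, LDHA, H2BC21, SNHG10, HOXA13 and PMAIP1 were listed at 0 with 6SG. On mean coverage against both controls AEBP2 stood at -0.03, RNF2 at -0.59, EZH2 at -0.53, SUZ12 at -0.04, MDM2 at -0.06 and HNRNPC at -0.08, and on covered length HNRNPH1 stood at 0.10.

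In limma with both PHC1 libraries, calls appeared when either control library stood alone and was assumed to vary like the PHC1 pair, and not with both controls. Without the 4SU library 4333 genes were higher and 1853 lower, without the 6SG library the counts were those just given, without PHC1 replicate 2 they were 4 and 0, and without PHC1 replicate 1 both were 0. RPL19, H2BC5 and TUG1, lower against 4SU alone, had folds above 0 against both controls, and the median of all genes was 0.04 with 4SU alone.

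The ChIP comparison of PHC1 dFCS with PHC1 asks whether loss of the FCS part changes PHC1 at promoters. The dFCS value was above the PHC1 value at 79.4% of all TSS rows (95% Wilson interval 78.8% to 80.1%), with a median log2 ratio of 0.25 (0.24 to 0.25). MYC had 5.30 reads per 10M (10M, 1e7) with PHC1 and 9.21 with dFCS, and EZH2, EED, another core PRC2 subunit, and POLR2A had log2 ratios of 0.72, 0.82 and 0.63. The median before input subtraction was 5.85 reads per 10M for PHC1 and 6.91 for dFCS, against 5.68 for input, and 0.0668 and 1.13 after it. These are the authors' means or values, with no SD or n, so no gene was tested, and single genes rest on few reads. The SD of the difference across genes was 1.43 reads per 10M. Counting error alone would give 1.31 for 2 averaged libraries and 1.85 for 1 library. Both assume the mean depth of the decoded ChIP libraries, 38.3M reads, as the depth of the PHC1 and dFCS libraries is not known. Scaled so that TSS rows of low PHC1 signal match in sum, the median ratio was 0.01 and 51.6% of rows were higher in dFCS, so the share of rows on each side depends on the scaling.

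The largest ratios in favour of dFCS were at MYOG, a muscle differentiation factor (Entrez 4656, chromosome 1, bases 203052257 to 203055166, 3.76 and 11.0 reads per 10M, log2 ratio 1.53), and at MMP13, a collagenase (1.41), TIAM1, a Rac activator (1.41), PEX5, the peroxisome import receptor (1.37), PEA15 (1.37), the phosphatase PTPRH (1.29), SPAG1 (1.28), GRAMD4 (1.27), CHSY1, which makes chondroitin (1.26), and the ubiquitin ligase CBL (1.25). The largest in favour of PHC1 were at HCG11 (chromosome 6, bases 26521934 to 26527612, 10.0 and 5.50 reads per 10M, log2 ratio -0.86), the gene with Entrez number 388199 (-0.85), CFAP91 of cilia (-0.84), PPP1R1B, a dopamine-regulated phosphatase inhibitor (-0.81), CCDC190 (-0.78), the interferon-induced IFI44 (-0.78), AGO1 of RNA silencing (-0.76), REP15 (-0.73), IFNL1, an interferon (-0.72), and MED1 of Mediator (-0.72).

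Of the 18 lists, 2 lay above the range of random lists with like ChIP values. That range was set for each list alone, with no correction for testing 18 lists. Some lists would thus fall just outside it by chance, so these 2 do not establish an effect on p53 targets or neuronal genes. The 10 p53 targets were all higher in dFCS, with a median of 0.48 at percentile 97.8, and ZMAT3 (0.68), PMAIP1 (0.66), GADD45A (0.63) and MDM2 (0.51) highest. Matched on nuclear RNA, a setting chosen after the data were seen, that percentile was 96.5, within the range. Neuronal genes had a median of 0.53 at percentile 98.2, with 6 of 7 higher in dFCS, such as ELAVL3 (0.67), the microtubule regulator STMN2 (0.58), NEFM (0.57) and INA (0.53). The other 16 lists lay within the range. Polycomb members were higher in 22 of 22, with a median of 0.40 at percentile 96.3, among them PCGF5 (0.89), EED (0.82), EZH2 (0.72) and PHC3, a PHC1 paralog (0.70), while RNF2 stood at 0.27. HOX genes were higher in 19 of 22 (median 0.36, percentile 91.6), such as HOXB13 (0.93), HOXC10 (0.80) and HOXA13 (0.62). Ribosomal protein genes had a median of 0.17 at percentile 6.52, and at 1.59 when matched on nuclear RNA, with RPS7 (0.96), RPS14 (0.87), RPS13 (0.50) and RPL24 (0.49) highest.

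Immediate early genes were higher in dFCS at 27 of 33 (median 0.28, percentile 70.8), with JUND (0.80), MYC (0.79) and the AP-1 member FOSL1 (0.72) highest. Heat shock genes were higher at 18 of 21 (median 0.26, percentile 54.4), such as DNAJB4 (0.68), HSPA8 (0.46) and CRYAB (0.40). Unfolded protein genes were higher at 10 of 11 (median 0.30, percentile 67.2), such as ATF4, the main factor of the integrated stress response (0.73), CHAC1 (0.54) and DDIT4 (0.46). Developmental factors were higher at 47 of 58 (median 0.28, percentile 68.9), such as ATOH1 of hair cells (1.05), FOXA1 (0.90), PAX7 of muscle stem cells (0.78) and WT1 of kidney (0.72). Splicing factors were higher at 19 of 25 (median 0.29, percentile 70.8), such as SF3B2 (1.01), LUC7L3 (0.84) and PRPF8 (0.66). Housekeeping genes were higher at 10 of 10 (median 0.26, percentile 54.8), such as TBP (0.47), B2M (0.47) and ACTB (0.43). Nuclear lncRNA were higher at 3 of 5 (median 0.19, percentile 36.2), with TUG1 at 0.76, NEAT1 at 0.19 and OIP5-AS1 at -0.37. The 3 replication histones (percentile 26.9) and 3 snoRNA hosts (59.5) were all higher, for example H2BC21 (0.31) and SNHG10 (0.70). Marker genes of fibroblasts (percentile 52.4, COL1A1 0.45), blood (24.9, HBB 0.60), hepatocytes (68.6, ALB -0.46) and keratinocytes (18.1, DSG3 0.56) lay within the range too.

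The next question is whether dFCS gained more where PHC1 bound more RNA. The 1443 genes with most PHC1 PAR-CLIP had a median log2 ratio of 0.27 at percentile 99.7, and those with most RNAPII PAR-CLIP 0.27 at 99.5. Against genes matched on nuclear RNA these percentiles were 69.7 and 61.4, so genes of like nuclear RNA had like ratios. The 936 genes with most PHC1 PAR-CLIP over nuclear RNA had a median of 0.25 at percentile 43.2, and 70.8 when matched on nuclear RNA, and the genes with most nuclear RNA 0.26 at 96.7. By chromatin, the 8925 TSS rows with H3K4me3 alone had 0.27 at percentile 100 and the 5239 rows with neither mark 0.20 at percentile 0, in both matchings. Rows with H3K27me3 alone had 0.20 at percentile 3.83 (37.2 matched on nuclear RNA), and rows with both marks 0.21 at 15.4. Across genes the ratio had a Spearman correlation of 0.107 with RNAPII ChIP, 0.105 with H3K4me3, 0.107 with nuclear RNA, 0.0805 with PHC1 PAR-CLIP, -0.0385 with PHC1 PAR-CLIP over nuclear RNA, -0.0799 with EZH2 and -0.113 with H3K27me3. From the lowest to the highest decile of RNAPII ChIP the median went from 0.23 to 0.30 and the share of rows higher in dFCS from 76.7% to 84.7%. By H3K27me3 ChIP they moved further and the other way, the median from 0.31 to 0.18 and the share from 85.6% to 73.1%.

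**Figure D2:**
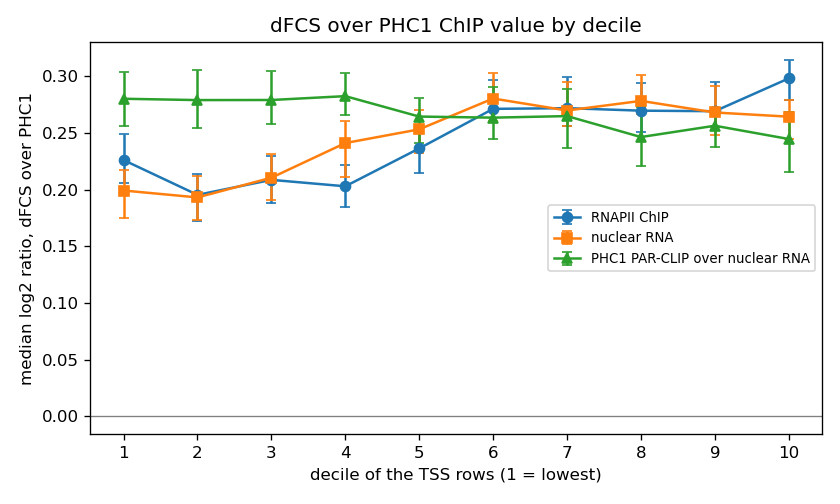
Median log2 ratio of dFCS over PHC1 ChIP (y axis) by decile of RNAPII ChIP, nuclear RNA and PHC1 PAR-CLIP over nuclear RNA (x axis). Bars are 95% intervals of the median over genes; for RNAPII ChIP the lowest decile is 0.23 and the highest 0.30, for nuclear RNA 0.20 and 0.26, and for PHC1 PAR-CLIP over nuclear RNA 0.28 and 0.24.

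PHC1 and EZH2 over input were higher at TSS rows that carry H3K27me3, the mark that PRC1 is known to bind through its CBX subunits, than at other rows. 95 rows had H3K27me3 and H3K4me3, 173 had H3K27me3 alone, 8925 (61.8%) had H3K4me3 alone and 5239 (36.3%) had neither. The median log2 of PHC1 over input was 0.14, 0.15, -0.00 and 0.02 in that order, that of dFCS 0.23, 0.22, 0.10 and 0.09, and that of EZH2 0.36, 0.27, -0.04 and 0.04. Before input subtraction PHC1 was flat across the classes, at 5.60, 5.87, 5.75 and 5.86 reads per 10M, while input was lower in rows with H3K27me3, at 4.13, 4.39, 5.94 and 5.68. EZH2 before input subtraction was higher in rows with H3K27me3, at 7.86, 7.27, 5.53 and 6.11 reads per 10M. With at least 20 input reads the PHC1 medians were 0.04, 0.07, -0.05 and -0.03. PHC1 and dFCS are here the authors' means or values, with no SD or n.

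The highest ratio of H3K27me3 to input was at SV2B, a synaptic vesicle protein gene (4.50-fold, with H3K4me3 at 12.1-fold), PROKR2, a prokineticin receptor gene (4.05), KIR3DX1 (3.97), PRDM12 of pain neurons (3.93), PAPPA (3.87) and RELN, which guides neuron migration (3.75), with PHC1 log2 values of 0.34, 0.24, 0.18, 0.26, 0.24 and 0.13. These rows had 11, 14, 12, 11, 10 and 12 input reads, against a median of 22 and a lowest of 10 over all rows. Both measures divide by that low input, so the ranking in part picks rows of low input. Of genes on the lists, NR4A2, an immediate early nuclear receptor, had both marks (PHC1 0.22), and LHX5, a factor of forebrain development and the highest developmental factor in PHC1, H3K27me3 alone (PHC1 0.20). Of 22 HOX genes, often Polycomb targets in other cells, 0 had H3K27me3 at this threshold, 14 had H3K4me3 alone and 8 neither, with HOXA4 highest in PHC1 (0.18). The HOX list has 39 genes, and those without a row could not be classed. No row of the deposited table had fewer than 10 reads in any decoded library. All 49 ribosomal protein genes had H3K4me3 alone, and some had the highest PHC1 of the lists, RPL10A (0.33), RPL32 (0.32) and RPS15 (0.30). JUNB (0.24), ATF4 (0.27), CRYAB (0.21), the p53 target FDXR (0.22), the PRC2 cofactor MTF2 (0.21), SRSF6 (0.23), MALAT1 (0.27) and EEF1A1 (0.24) were the highest of their lists. Of the 58 developmental factors 42 had H3K4me3 alone and 14 neither. Of 33 immediate early genes 30 had H3K4me3 alone, and all 22 Polycomb members did. Blood, hepatocyte and keratinocyte markers all had neither mark, and of 6 fibroblast markers 5 had neither.

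**Figure D3:**
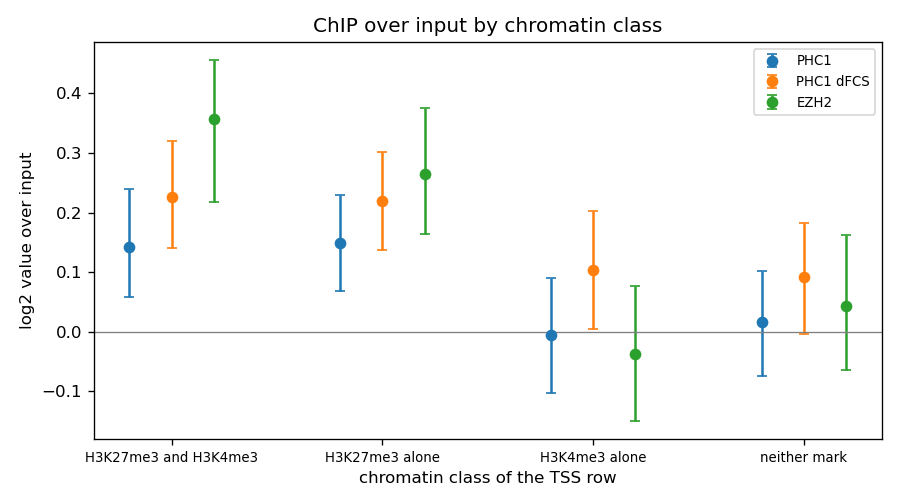
Median log2 over input of PHC1, PHC1 dFCS and EZH2 ChIP (y axis) by chromatin class (x axis), with bars from the lower to the upper quartile of rows. PHC1 medians are 0.14 with both marks, 0.15 with H3K27me3 alone, -0.00 with H3K4me3 alone and 0.02 with neither.

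Across TSS rows PHC1 over input went with EZH2 (Spearman 0.561) and H3K27me3 (0.511) more than with RNAPII (0.189) and H3K4me3 (0.135). Division by the same input raises such values by itself: with the reads of 1 target shuffled among genes they were 0.454, 0.407, 0.247 and 0.189. Without division by input they were 0.366, 0.312, 0.213 and 0.192. PHC1 and dFCS had 0.664 (0.506 shuffled, 0.497 without input). dFCS had 0.534 with EZH2 (0.476 shuffled), 0.453 with H3K27me3 (0.427), 0.285 with RNAPII (0.258) and 0.227 with H3K4me3 (0.198). Without division by input the order was the reverse for dFCS, with 0.329 for RNAPII and 0.306 for H3K4me3 above 0.298 for EZH2 and 0.209 for H3K27me3. EZH2 and H3K27me3 had 0.577 (0.375 shuffled), and H3K4me3 and RNAPII 0.832 (0.0366 shuffled). SUZ12, EZH2 and MYC, named above for their RNA, all lay in the class with H3K4me3 alone.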

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

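The tests in this part were chosen after the results were seen, except 2 written before: the one on copy number and the one on H3K4me3 at TSS rows of low RNAPII. 3 places with deep clusters that were given to no gene region, and so not used in the comparisons, held more of the summed PHC1 PAR-CLIP coverage than of either RNAPII library. The mitochondrial genome held 3.38% and 2.58% in the PHC1 replicates, against 0.302% with 4SU and 0.285% with 6SG. Bases 9825439 to 9827583 of chromosome 21 held 9.38% and 4.86%, against 0.924% and 0.198%. Bases 79186669 to 79186886 of chromosome 9 held 6.04% and 0.220%, against 0.0139% and 0. What these sites are was not tested, and shares within a library depend on what else it holds.

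PHC1 over input was higher at rows with H3K27me3. Copy number of the surrounding region cannot be told apart from it: given the input of the row and of its 20 nearest rows, PHC1 and H3K27me3 before input subtraction still correlated at 0.201 (0.185 to 0.217), but the interval spans the bound of 0.2, and how the interval counts was settled only after the value was seen. Low input reads in rows picked by their ratio to input may account for the class medians, since PHC1 before subtraction differed by 0.0113 reads per 10M (-0.281 to 0.269) between rows with H3K27me3 alone and with neither mark. More PHC1 where there is more H3K27me3 stays open too, since at equal input the highest decile of H3K27me3 had 1.08 reads per 10M more PHC1 than the lowest (0.947 to 1.12).

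The dFCS value lay above the PHC1 value at most rows, and more so at rows with high RNAPII. For the level at most rows a single scaling factor between the pooled columns stays open: scaled to rows of low PHC1 signal the median log2 ratio was 0.012 and 51.6% of rows were higher, which this scaling brings about by construction. A single factor leaves all deciles alike, so it alone cannot give the rise with RNAPII. The highest decile exceeded the lowest by 0.0721 (0.0433 to 0.0962), the value that defines this rise, so this is arithmetic and no separate test. PHC1 binding to RNA beyond RNA abundance was tested over 9362 genes. Given nuclear RNA, the ratio had a partial correlation of -0.0326 (-0.0527 to -0.0128) with PHC1 PAR-CLIP over nuclear RNA, so it did not rise with that measure. The test holds no RNAPII value and leaves out genes under the low-value filter, so it cannot decide the rise with RNAPII. Accessible chromatin caught at H3K4me3 rows whatever their RNAPII cannot be told apart, since the correlation of the ratio with H3K4me3 at 7273 rows of low RNAPII was 0.0606, between the bounds set in advance. Differences between the immunoprecipitations or in protein level stay open, as the pooled columns show no spread between replicates.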

How the results depend on the processing

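Alternatives were fixed before the data were examined, except the following, which were chosen after seeing the data: pseudocount 10, major strand, without the deepest clusters, covered length, mean coverage, DESeq2 on cluster numbers, edgeR on cluster numbers with 4SU alone, cluster numbers against RNA, the 4SU library alone for the lists, 20 input reads for the dFCS ratio, unmatched lists, differences in place of ratios, and lists matched on nuclear RNA. Of the values of named genes and list members under alternatives, 2668 kept their direction and side of the threshold, 401 passed it where they had not, 52 no longer passed it and 117 changed sign. Of the main values of the comparisons under alternatives, 122 were the same, 39 moved, 17 passed a threshold, left the random range or called more genes, 14 no longer passed, lay within that range or called fewer, and 1 changed sign. These counts leave out the camera tests against nuclear RNA, where immediate early, heat shock, developmental, ribosomal protein and housekeeping genes each went to an adjusted p = 0.614 with an estimated correlation. That setting has few degrees of freedom, as given above, so hardly any list could pass in it. For each change given here the cause was not tested, unless stated.

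For PHC1 PAR-CLIP against nuclear RNA, counts of genes stayed within 1.5 times under other size factors, no TMM, no filter, a replicate block (3255 higher and 4423 lower), pseudocount 10, major strand, cluster numbers and without the deepest clusters. A mean of at least 50 left 4544 genes to test and gave 2012 higher and 1821 lower, from fewer genes. Leaving out each library in turn gave 2830 to 3021 higher and 2779 to 5097 lower, lowest without RNA replicate 1 (2779) and RNA replicate 2 (2780), where the lone RNA library is assumed to vary like the PHC1 pair. No named gene of this comparison changed sign but on cluster numbers: ASNS -0.11, MDM2 -1.0, LUC7L3 -0.27, TUG1 -0.67 and MALAT1 -4.70.

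For PHC1 against RNAPII PAR-CLIP, 0 genes were called by limma with other size factors, no TMM, other filters, pseudocount 10, major strand, covered length, mean coverage or without the deepest clusters, against 1195 higher and 648 lower at an unadjusted p under 0.05 in the main setting. 2707 higher and 2248 lower were called with 4SU alone, 1211 and 1083 by edgeR on cluster numbers, 3 and 3 by DESeq2 on them, and 1642 and 1542 by edgeR with 4SU alone. Leaving out each library gave 0 to 4333 higher (4 without PHC1 replicate 2, 4333 without the 4SU library, 2707 without the 6SG library) and 0 to 2248 lower (1853 without 4SU, 2248 without 6SG). Adjusted p for immediate early genes was 0.738 with an estimated correlation and 0.118 with 4SU alone, for developmental factors 0.738 and 0.359, for HOX genes and splicing factors 0.738 with an estimated correlation, and with 4SU alone 0.0164 for heat shock (median -0.71, from 1.50) and 0.0158 for ribosomal proteins (median -0.79, from 0.82).

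BAX, C22orf46P, CCDC112, FKBP4, H2BC21, HOXA13, LDHA, LRP2, PGK1, PMAIP1, RPS6, SMARCA1, SNHG10 and TBX3 were listed at 0 with 6SG, so their folds against both controls or 6SG alone are set in part or whole by the pseudocount and are no measured changes of direction. Log2 folds against RNAPII changed sign as follows. With 4SU alone: H2BC21 -1.0, H3C10 -0.24, H2BC5 -1.53, SNHG10 -0.97, MALAT1 -1.50, TUG1 -0.63, PGK1 -0.24, INA 0.27, POLR2A -0.086, FKBP4 -1.51, PMAIP1 -0.74, HOXA13 -1.77, RPS6 -1.93, RPL19 -1.40 and LDHA -1.08. On mean coverage: MDM2 -0.060, HAND2 0.28, SUZ12 -0.043, AEBP2 -0.034, TUG1 -0.41, INA 0.072, RNF2 -0.59, EZH2 -0.53, POLR2A -0.33, MAP3K19 -0.64 and HNRNPC -0.084. On covered length: STIP1 0.28, H2BC5 -0.17, HNRNPA2B1 0.70, SRSF11 0.053, CHORDC1 0.029, GATA6 0.23, HNRNPH1 0.10 and SF3B1 0.48. On cluster numbers by edgeR: BAX -0.023, H3C10 -1.16, H2BC5 -0.75, MALAT1 -1.60, TUG1 -0.48, POLR2A -0.32, FKBP4 -0.70, PMAIP1 -0.37, RPS6 -1.21, RPL19 -0.39 and LDHA -0.39. By DESeq2 on them: H3C10 -1.05, H2BC5 -1.03, SRSF11 0.031, MALAT1 -1.66, TUG1 -0.36, POLR2A -0.36, FKBP4 -0.21, GATA6 0.077, RPS6 -0.74, RPL19 -0.25 and SF3B1 0.10. By edgeR with 4SU alone: PPP1R15A 0.088, BAX -0.074, H3C10 -1.14, H2BC5 -0.61, SNHG10 -0.89, MALAT1 -1.54, TUG1 -0.46, POLR2A -0.26, FKBP4 -0.76, PMAIP1 -0.42, RPS6 -1.27, RPL19 -0.38 and LDHA -0.44. Without TMM: H2BC5 -0.14, TUG1 -0.13 and POLR2A -0.065. With pseudocount 10: H2BC5 -0.015. Leaving out each library in turn gave these ranges: H3C10 -0.24 to 1.19, H2BC5 -1.53 to 1.72, MALAT1 -1.50 to 3.12, TUG1 -0.63 to 0.84, INA -2.33 to 0.27, POLR2A -0.086 to 0.43, MAP3K19 -0.034 to 5.63, ANK3 -3.72 to 0.31, CHORDC1 -1.42 to 0.50, RPL19 -1.40 to 2.77 and SF3B1 -1.57 to 1.27. For the genes listed at 0 with 6SG, the values set by the pseudocount were, on mean coverage, C22orf46P 2.05, SMARCA1 2.39, LRP2 3.34, CCDC112 2.42 and TBX3 2.74, on covered length, C22orf46P 0.12, SMARCA1 0.22, CCDC112 0.79 and TBX3 0.49, with pseudocount 10, HOXA13 -0.18, and for TBX3 0.014 with DESeq2 size factors, 0.056 on the major strand and 0.016 without the deepest clusters. Their ranges over left-out libraries, of which the upper ends rest on the pseudocount, were H2BC21 -1.0 to 5.34, SNHG10 -0.97 to 4.03, PGK1 -0.24 to 6.33, LRP2 -3.75 to 3.39, CCDC112 -3.60 to 3.36, FKBP4 -1.51 to 5.61, PMAIP1 -0.74 to 6.38, HOXA13 -1.77 to 0.89, TBX3 -2.62 to 0.25, RPS6 -1.93 to 6.22 and LDHA -1.08 to 4.38.

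For ChIP, scaling to TSS rows of low PHC1 signal moved the median log2 ratio of dFCS over PHC1 to 0.012 and the share of rows higher in dFCS to 51.6%, by its construction, since it sets the summed values of the lower-signal rows equal. Set percentiles matched on nuclear RNA were 69.7 for PHC1 PAR-CLIP and 61.4 for RNAPII PAR-CLIP, and the latter was 96.5 for differences. The top quintile of nuclear RNA gave 99.9. Matched on nuclear RNA, p53 targets were at 96.5 and ribosomal proteins at 1.59. With a pseudocount of 0.1 CPM the class medians of PHC1, in the order both marks, H3K27me3 alone, H3K4me3 alone and neither, were 0.35, 0.39, -0.011 and 0.039, and of dFCS 0.56, 0.52, 0.23 and 0.20, as a smaller pseudocount widens log ratios by construction. With at least 20 input reads they were 0.040, 0.073, -0.053 and -0.029 (a change of sign for neither mark), and for dFCS 0.14, 0.15, 0.056 and 0.047. Correlations of PHC1 without division by input were 0.366 with EZH2, 0.312 with H3K27me3, 0.192 with H3K4me3, 0.213 with RNAPII and 0.497 with dFCS, and with at least 20 input reads 0.434, 0.393, 0.112, 0.135 and 0.542. Those of dFCS without input were 0.298 with EZH2, 0.209 with H3K27me3, 0.306 with H3K4me3 and 0.329 with RNAPII, and with at least 20 input reads 0.388, 0.308, 0.220 and 0.248. EZH2 and H3K27me3 had 0.410 and 0.476. Cluster overlap with at least 50% of the cluster covered was 59.99% for replicate 1 in 2 and 63.9% for 2 in 1. With at least 1 base shared and only the upper 50% of clusters by score in both libraries, it was 66.3% and 73.4%.

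No paired analysis was possible because the dFCS and PHC1 ChIP values are pooled columns without replicates. For the same reason DESeq2, other size factors, no TMM, count filters, leaving out libraries, a threshold of 0.1, a replicate block and camera with an estimated correlation were not run for dFCS against PHC1 or its sets and lists. The choice of 1 TSS per gene was not run since the table has 1 row per gene. DESeq2 on summed PAR-CLIP coverage was not run since it is no count. A 4-fold class threshold left 1 row in each class with H3K27me3, too few for a value. With a median of 20 reads per TSS for EZH2, 18 for H3K27me3 and 22 for input, depth limits ChIP values of single genes.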

Other observations

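The gene set and the tests of this part were chosen after the data were seen. 55 genes had nuclear RNA under 1 CPM and a PHC1 PAR-CLIP per-million value, here without TMM, of at least 20 in both libraries. Besides UNC45B, PPEF2 and CPNE7 they include GAL3ST1 (229 and 276, RNA 0.691 CPM), CCL5 (180 and 196, RNA 0.196 CPM), the sulfotransferase gene GAL3ST2 (95.2 and 180), ST6GALNAC1, a sialyltransferase gene (164 and 170), and TPPP3, a tubulin-binding protein gene (267 and 172). Genes known from other cell types are among them, such as ELAVL3 (55.4 and 84.1) and RBFOX1 (41.7 and 61.7) of neurons, the prothrombin gene F2 of liver (42.3 and 65.5), and GZMM of cytotoxic lymphocytes (29.2 and 46.2). LINC00273 had 395 and 209 with RNA listed at 0.

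1 candidate explanation is that a single very deep cluster per gene, as from misplaced reads, makes up the signal. It is argued against for the set, where the median gene had 27.3% and 28.0% of its PHC1 coverage in its largest cluster, though not for single genes such as TPPP3 (83.3% and 81.9%). Several deep clusters per gene stay open, since the largest cluster alone cannot show them. UNC45B, with only 4 and 10 clusters, had 52.0% and 33.8% in its largest. Another candidate is that RNA is made in these regions but lies outside the RNA counts, for example in introns. It cannot be told apart: 38.2% of the genes (21 of 55) had RNAPII 4SU PAR-CLIP of at least 5, between the bounds chosen for it. Whether the signal comes from the other strand or an overlapping transcript was not tested.

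Among places given to no gene region, bases 120729558 to 120730944 of chromosome 12 held 2.86% of the RNAPII 4SU coverage and 0.144% and 0.177% of the PHC1 coverage. Bases 52860705 to 52860750 of chromosome 6 held 5.23% of the 6SG coverage. 47.2% of the 6SG clusters shared a base with a 4SU cluster, and 40.8% and 36.9% with a PHC1 cluster of replicate 1 and 2.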
